A study of Mus musculus with 2 samples.

How the data were processed

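Total RNA from newborn mouse lenses was measured on Agilent 1-colour gene expression arrays, with 1 array for control lens and 1 array for lens labelled as a lens-specific Foxp1 knockout. Lenses were frozen and the RNA was taken with Trizol, per the labels' protocols. Each RNA was labelled with Cy3. The labels give the age as postnatal day 0 and a mixed C57BL/6 background, and they call the control a wild-type litter mate. The treatment text of both samples names the floxed Foxp1 allele and the lens Cre driver, so the grouping was taken from the source and genotype labels. Whether lenses of several animals were pooled is not stated in the labels. Both arrays lay on the same slide and were scanned under the same protocol, so array position and genotype cannot be told apart.

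The values used are intensities of single spots on a linear scale, deposited as scanner output. Per the file headers, they were extracted with Agilent Feature Extraction 10.7.3.1 at a scan resolution of 3 microns, with a probe layout annotated to the mouse build mm9. The processed signal of the files is the spot brightness after background subtraction by that software. Flags for outlier spots, saturation and a signal well above background come from the same files. These flags are the authors' deposited yes or no values. No scaling between arrays is recorded in the file headers.

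From these intensities, spots flagged as outliers on either array were left out, which removed every spot of 26 probes. Control spots were also left out. The log2 of each processed signal was taken, and the 75th percentile of the array was subtracted. Spots of a probe were averaged. A probe counted as measured when more than 50% of its spots were well above background on both arrays. The difference of a gene was the mean over its measured probes of the knockout value minus the control value. A gene above background on 1 array only was given a bound. The bound set the bright value against the dim probe's own value or the lowest spot signal called well above background on the dim array (20.6 for the control array and 12.1 for the knockout array), whichever was higher.

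The files carry accessions and not gene symbols, so probes were named by matching unversioned RefSeq transcript accessions to a table of the GRCm38.p6 annotation. Of the 55655 probes left after flags, 27225 received a gene symbol and 28430 did not. The matched probes covered 20655 genes, of which 14254 were measured on both arrays and 4087 were above background on neither. Because the arrays were laid out on another build, the GRCm38.p6 table was used only for names and for which genes neighbour each other. No coordinates are given.

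With 1 array per genotype no test across samples was possible, and no p-value is given. A fixed rule of size was used in its place, a difference of at least 2-fold (1 on the log2 scale). Technical error was estimated from 281 probes printed at least 5 times on each array. The SD of a spot difference between the arrays was 0.17 on the log2 scale over all such probes and 0.11 for probes at or above the median signal. This error covers spot noise only. It does not cover differences between animals, dissections or labelling reactions. The mean over the probes of a gene carries a smaller spot SD. For the 57 probes in the dimmest of 5 signal classes the pooled spot SD was 0.28. Genes dimmer than the median of that class were given the same value, so their noise may be larger. The number of arrays limits the precision of every value.

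Before the data were examined, 29 gene lists were fixed for lens tissue, signalling and stress responses, and cell types that a dissected lens could carry. For each list the median difference of its measured members was set against 10000 random lists of the same size, matched on mean signal in 10 classes. The percentile obtained describes this pair of arrays and is not a test. A further 3 lists, of retinal progenitor, ATF4 amino acid and SRF and YAP target genes, were chosen after the data were seen. Confidence intervals are 95% intervals. Those of shares are exact binomial intervals, and those of list medians come from 10000 bootstrap resamples of the members.

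The genes named in the text follow a rule fixed before the data were examined. It takes Foxp1 to Foxp4, and the 12 genes with the largest difference in each direction among genes at or above the median signal. Each of those genes had every probe measured and at least 2-fold apart the same way, and predicted or unnamed genes were passed over. The rule further takes up to 5 genes with the largest bound in each direction and up to 4 members of each list with the largest difference. Other genes are named only where stated, and some genes that the rule takes are not reported here.

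The steps were tested on simulated data, in which 14254 genes carried the measured spot noise alone and 200 of them were given a difference of known size. All genes made 3-fold different were recovered (100%), 1% of genes made 1.5-fold different were called, and 0 unchanged genes were called. In the same simulation a list of 25 genes shifted by 0.5 on the log2 scale returned a median of 0.46 and a percentile of 100.

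Alternatives covered the scaling (array median, 75th percentile over measured probes, none beyond the processed signal, quantile normalization, and loess of the difference on the mean signal with a span of 0.3), the filter on dim probes, outlier spots, the brightest probe in place of the mean, and the size threshold. After the data were seen, normexp background correction on the median signals with an offset of 50 was added, as was loess together with the brighter probes. The planned normexp correction on mean signals was replaced by that one, since the files hold median and not mean spot signals. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and R 4.3.3 with limma 3.58.1.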

Results

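Gene expression was profiled in the lens of newborn mice in which the forkhead transcription factor Foxp1 had been deleted in the lens, and in the lens of control litter mates. The series held 2 samples, 1 control array and 1 knockout array, both at postnatal day 0. Each array carried 59305 spots for genes, which made up 55681 probes. On the control array 67.5% of these spots were well above background, against 56.9% on the knockout array. The 75th percentile of the processed signal was 283 on the control array and 279.9 on the knockout array, whereas the medians were 50.2 and 23.6. No spot was saturated on either array (0 spots each), and the brightest spots read 477610 and 479035. After scaling, the median difference of the 14254 genes measured on both arrays was 0.01 on the log2 scale, with an SD of 0.53 over genes. Because each genotype had 1 array, no difference below has a replicate check, and each is a difference between these arrays. Direction is given relative to scaling by the 75th percentile, and scaling by the array medians raised every gene by 1.08, so that any gene lower by less than this changed direction, and placed the median of each gene list described below above 0.

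Foxp1, the targeted gene, read lower on the knockout array with all 3 of its probes. The brightest probe had a processed signal of 3460.2 on the control array and 969.9 on the knockout array, a log2 difference of -1.82. The other two probes read 1677 and 97.5 on the control array against 464 and 38.4 on the knockout array, differences of -1.84 and -1.33. A spike-in RNA as dim as the last probe, at 81.0 and 38.3, differed by -1.07. The dimmest probe therefore adds little to the brighter ones. The mean difference was -1.66 ± 0.29 (SD over 3 probes), a 3.17-fold lower signal. Among the genes at or above the median signal, 5 were as low or lower, Foxp1 included. The labels do not say which exons were removed, so where the probes lie relative to the deleted part is not known here, and the residual signal does not measure how complete the deletion was. The related gene Foxp4 was measured with 2 probes, with differences of 0.18 and 0.38. Foxp2 and Foxp3 were dim. The brighter Foxp2 probe read 56.6 on the control array and 13.7 on the knockout array, and the Foxp3 probe read 25.6 and 8.70. None of the knockout readings of Foxp2 or Foxp3 was well above background.

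**Figure D1:**
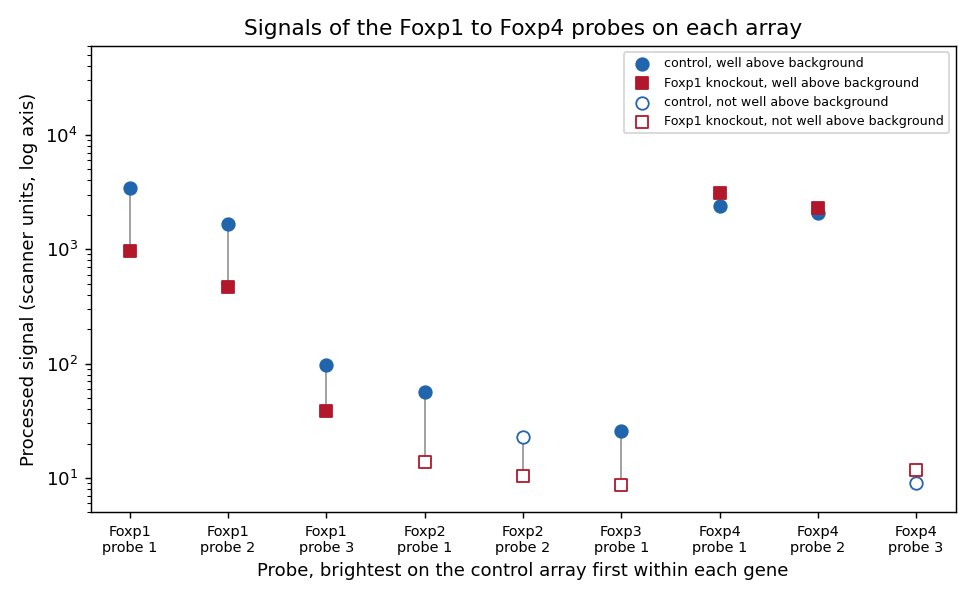
Processed signal in scanner units on a log axis for each probe of Foxp1, Foxp2, Foxp3 and Foxp4, with circles for the control array and squares for the Foxp1 knockout array. Filled symbols were well above background and open symbols were not. The 3 Foxp1 probes read lower on the knockout array (3460.2 against 969.9 for the brightest), and the 2 measured Foxp4 probes lay within 0.38 on the log2 scale.

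Which lens transcripts differed when Foxp1 was deleted was asked across all measured genes. Among bright genes the largest difference belonged to Omp. This gene, the olfactory marker protein, read 207 on the control array and 3757 on the knockout array, which is 18.3-fold higher. Cntn1, a neural cell adhesion protein, was 16.1-fold higher, from 582 to 9295. Abhd8, a hydrolase domain protein, was 11.3-fold higher. Znrf1, a ubiquitin ligase, and the membrane protein gene Mmd had log2 differences of 3.46 and 3.45, and the signal of Mmd reached 13632. Tnfsf9, a ligand of the TNF family, was 9.46-fold higher. Chac1, which degrades glutathione, was 8.99-fold higher. Each of these genes was read by a single probe. The genes Fgf12, Asah1 and Capn5 were each read by 2 probes, both above 2-fold. Fgf12, a fibroblast growth factor homologue that acts on sodium channels, was 6.34-fold higher, with probe differences of 2.53 and 2.80. Asah1, acid ceramidase, was 5.15-fold higher and the calpain protease Capn5 was 4.95-fold higher. Pros1, protein S, was 5.22-fold higher. Acta2, smooth muscle actin, was 4.27-fold higher, from 914 to 3865. Omp lies inside the span of Capn5 in the GRCm38.p6 annotation, so the readings of the pair are uncertain as separate measurements.

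The largest lower signals among bright genes included Foxp1 itself. Capn11, a calpain protease, was 4.20-fold lower on the knockout array, from 1400.1 to 330.1, and Clic5, a chloride channel family protein linked to the actin cortex, was 4.07-fold lower. The membrane protein gene Susd2 was 3.46-fold lower. Crabp2, a retinoic acid binding protein, was 3.13-fold lower, from 6800.0 to 2153. The cytoskeletal genes Tuba1a, an alpha tubulin, and Kif5c, a kinesin motor, were 2.94-fold and 2.91-fold lower. Tuba1a has near-identical paralogs, so its probe reading is uncertain. Tas2r109, a bitter taste receptor gene, was 2.79-fold lower at signals of 19356 and 6874. Ckmt1, a mitochondrial creatine kinase, was 2.77-fold lower. The connexin gene Gjb1 was 2.55-fold lower and the vasopressin gene Avp was 2.54-fold lower. Apart from Foxp1, each of these genes was read by 1 probe. For these bright genes in either direction the spot SD lay between 0.07 and 0.12 on the log2 scale, far below the differences.

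Among the 7127 genes at or above the median signal, 60 were at least 2-fold higher on the knockout array and 28 were at least 2-fold lower. Spot noise alone gave 0 such calls. Of 21 genes whose brightest of several probes was bright and at least 2-fold higher, 11 had all other probes at least 2-fold higher as well, and of 12 such genes on the lower side 1 did. Lower genes made up 31.8% of these calls (exact 95% interval 22.3 to 42.6), 42.9% after loess (32.1 to 54.1) and 53.8% with the 75th percentile taken over measured probes (43.1 to 64.2). Over all 14254 measured genes the split was the other way, with 146 higher and 835 lower, because 807 of the lower genes were among the 7127 dimmer genes, where 86 were higher. Spot noise alone gave on average 0.32 higher and 0.35 lower calls over all genes. The split over all genes depended on the scaling. Array medians gave 8724 higher and 101 lower, quantile normalization gave 776 and 232, loess gave 259 and 381, and normexp correction, added after the data were seen, gave 72 and 99. Probes for added E1A spike-in RNAs also read lower on the knockout array when dim. The 3 dimmest had a median difference of -2.46, against -0.03 for the 5 spike-ins above a signal of 1000. The brightest of the 3 read 81.0 and 38.3, a difference of -1.07. The others fell below the lowest signal called well above background on the knockout array.

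**Figure D2:**
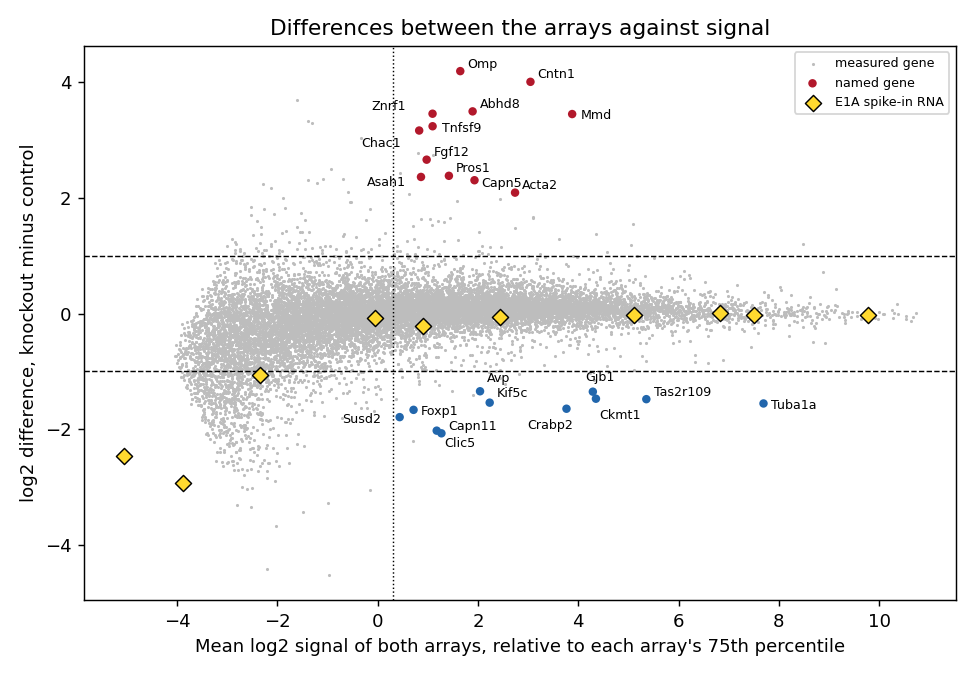
Log2 difference, knockout minus control, against the mean log2 signal of both arrays relative to each array's 75th percentile. Grey points are the 14254 measured genes, red and blue points the named genes with the largest differences, and diamonds the E1A spike-in RNAs. Dashed lines mark 2-fold and the dotted line the median signal of genes. Dim genes and dim spike-ins spread downward (median -2.46 for the 3 dimmest spike-ins), and bright spike-ins lay near 0 (median -0.03).

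Some genes were above background on 1 array only. There were 472 such genes on the knockout array, of which 30 were at least 2-fold higher. The largest bound belonged to Rnf19a, a ubiquitin ligase gene, which was at least 82.8-fold higher with a signal of 1691 on the knockout array and 5.44 on the control array. Dcn, the proteoglycan decorin, was at least 7.18-fold higher. The ribonuclease gene Rnase2a was at least 6.72-fold higher, the forkhead factor Foxa1 at least 6.29-fold higher and the lipid transporter Abca8b at least 5.40-fold higher. Each of these higher genes was read by 1 probe. On the control array alone 1809 genes were above background, and 1679 of these were at least 2-fold lower on the knockout array. Bounds that start from a control signal below 100 share the dim range in which the spike-ins read lower. The largest bounds were those of the vomeronasal receptor gene Vmn1r124, at least 66.7-fold lower, and of Kel, a blood group metalloprotease gene, at least 36.7-fold lower. Their control signals were 817 and 449. Tex15, Parp14 and Cd209g were at least 26.1-fold, 25.2-fold and 23.5-fold lower, from control signals of 320, 309 and 288. Spike-ins at control signals of 280 and 566 differed by only -0.07 and -0.21, so these named genes lie outside that dim range. Apart from Tex15, with 2 probes, each of these lower genes was read by 1 probe.

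Genes of the differentiated lens were close to equal on both arrays. All 16 crystallins, the structural proteins of the lens, lay between the 2-fold limits, with 7 above and 9 below 0. Their median difference was -0.01, and its sign depended on the scaling, with 0.04 after loess. Cryba2 was highest at 0.16 and Crybb3 lowest at -0.13. Crygs and Cryba4 both lay at -0.09. The median crystallin signal was 351036 on the control array and 351426 on the knockout array, close to the brightest spots of the arrays, where differences can be compressed. Of 19 measured lens fibre genes 0 passed 2-fold, 11 lay above and 8 below 0, and the median was 0.04. Lgsn, lengsin, was lowest at -0.67, and Epha2, Slc2a3 and Jag1 lay at 0.42, 0.41 and 0.40. Lens epithelium genes had a median of -0.10, with 0 of 16 beyond 2-fold, 5 above and 11 below 0. Their median lay at percentile 0.90 of matched random lists and at 13.2 after loess, where it was -0.05, and it turned above 0 with the brightest probe of each gene (0.01) or the brighter probes alone (0.04). The gap junction gene Gja1 read -0.70, the water channel Aqp1 -0.54 and clusterin, Clu, -0.39, whereas the epithelial factor Foxe3 read 0.34. Of 20 lens transcription factors, 5 of them also on the epithelium list, 0 passed 2-fold, 14 lay above and 6 below 0, and the median was 0.13. Gata3, Sox2, Sox11 and Hey1 had differences of 0.69, 0.55, 0.54 and 0.53. The measured Foxp family members held 1 lower gene, Foxp1, and 1 between the limits, Foxp4.

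Cell cycle genes were higher on the knockout array as a group, though no member reached 2-fold. Of 26 measured members 25 lay above 0 and 1 below, with a median difference of 0.46, or 1.37-fold, and an SD of 0.20 over members. Their median exceeded that of all 10000 matched random lists, a percentile of 100, whose medians centred on 0.07. It stayed above 0 under each scaling and filter tried, and between 0.34 and 0.60 when taken relative to the median of all genes. Cdc20, an activator of the anaphase-promoting complex, read 2009.8 on the control array and 3380 on the knockout array, a difference of 0.76. The spindle checkpoint kinase Bub1 and the replication helicase subunit Mcm3 each had a difference of 0.60. Cyclin D, Ccnd1, was 0.59 higher at a signal of 23773. Retina markers were higher as well. Of 13 measured, 12 lay above 0, 1 passed 2-fold, and the median was 0.45 at a percentile of 100. The ganglion cell factor Pou4f2 was 2.53-fold higher, from 109.9 to 275, Isl1 had a difference of 0.995, and the neuronal genes Nefl and Stmn2 had differences of 0.95 and 0.89.

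Of 11 cell cycle exit genes 2 were at least 2-fold higher, 1 was at least 2-fold lower and 8 lay between. The median was 0.05, and became 0.25 with the brightest probe of each gene, 0.32 over the brighter probes and -0.02 after loess. Cdkn1a, an inhibitor of cyclin-dependent kinases, was 2.65-fold higher on average over 2 probes that disagreed, at 0.09 and 2.72. Cdkn2c was 2.04-fold higher. Cdkn2a was 2.03-fold lower, a dim reading of 123 against 60.05. Cdkn2b lay at -0.61. The p53 target genes were mostly above 0, 15 of 16 measured, with 3 at least 2-fold higher, 0 lower and a median of 0.31 at percentile 99.99. The median was 0.13 over the 11 brighter members and 0.17 after normexp correction. Cdkn1a is on both lists and, like Gdf15, was dim. Gdf15, a stress cytokine, was 3.56-fold higher at signals of 41.8 and 147, and Phlda3, an inhibitor of Akt, was 2.68-fold higher, from 704 to 1865. The apoptosis gene Pmaip1 had a difference of 0.82. The list's one member below 0 was Mdm2, the ubiquitin ligase for p53, at -0.53, a gene named here after its value was seen.

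**Figure D3:**
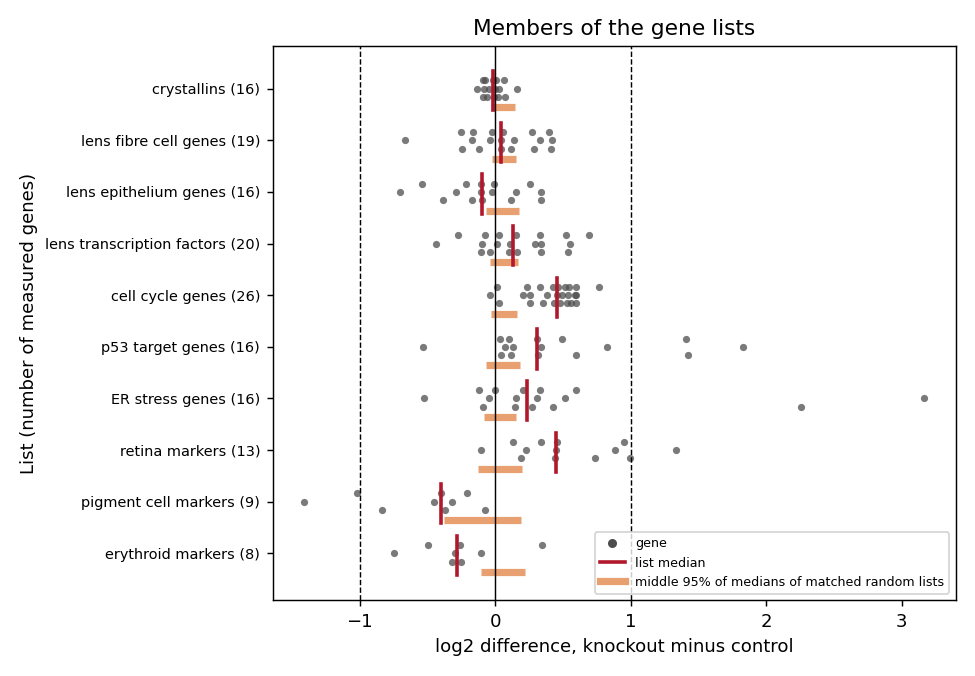
Log2 difference, knockout minus control, of each measured member of 10 gene lists, with the number of measured genes in parentheses. Red lines are list medians, and orange bars hold the middle 95% of the medians of 10000 random lists matched on signal. Cell cycle genes (median 0.46) and retina markers (0.45) lay to the right of their bars, while crystallins gathered near 0 (median -0.01).

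Stress response lists differed in part. Of 16 endoplasmic reticulum stress genes 2 were at least 2-fold higher and 0 lower, 11 lay above 0, and the median was 0.24 at percentile 99.93, or 0.16 after loess. Beside Chac1, Trib3, a pseudokinase of the same response, was 4.78-fold higher at signals of 56.1 and 265. Herpud1 had a difference of 0.60 and Hyou1 one of -0.53. Heat shock genes split, with 1 higher and 1 lower of 10 measured and a median of 0.07. The chaperone gene Hspb8 was 2.39-fold higher, from 273 to 648. Hspa1a was 2.45-fold lower at dim signals of 43.8 and 17.7. Hsph1 and Hspb1 lay at 0.67 and 0.46. Of 13 antioxidant genes 1 was at least 2-fold higher, with a median of 0.15. The metallothionein genes Mt2 and Mt1 were 2.18-fold and 1.99-fold higher, and Slc7a11 and Gclc lay at -0.40 and -0.24. No cholesterol synthesis gene passed 2-fold (0 of 14), 11 lay above 0, and the median was 0.17, with Dhcr7 at -0.65, Hmgcs1 at 0.59 and Msmo1 at 0.48. Of 14 hypoxia and glycolysis genes 1 was higher, 0 were lower and 9 lay below 0, with a median of -0.17 at percentile 0.30 that turned to 0.00303 under quantile normalization. Against that direction Car9, a carbonic anhydrase, was 9.85-fold higher, from 36.4 to 355, read by 1 probe. Pfkfb3, Ndrg1 and Egln3 lay at -0.60, -0.58 and -0.54. Interferon response genes were all dim. Of 8 measured, 2 were at least 2-fold lower and 7 lay below 0, with a median of -0.80 at percentile 2.78, or -0.18 under quantile normalization. Ifi44 was 6.56-fold lower, from 106 to 15.9 and Isg15 was 2.08-fold lower. Ifit3 lay at -0.88 and Oasl2 at 0.87. No immediate early gene passed 2-fold (0 of 8), with a median of 0.13. Ier2 and Junb lay at -0.89 and -0.66, and Egr1 and Ccn1 at 0.73 and 0.40.

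Among growth factor responses, 1 of 12 measured genes of the FGF and ERK pathway was at least 2-fold higher and 0 were lower, with a median of 0.09 that became 0.27 under quantile normalization, 0.38 over the brighter probes and -0.03 with the 75th percentile taken over measured probes. The ETS factor Etv4 was 2.23-fold higher, with 2 probes at 1.12 and 1.20. The feedback inhibitor Spred2 lay at -0.82 at a dim signal, while Spry1 and Etv5 lay at 0.51 and 0.45. Of 13 measured genes of the BMP and TGF-beta response 1 was higher, 1 lower and 11 between, with a median of -0.04. Ccn2, a matricellular growth factor, was 3.19-fold higher, from 1352 to 4273. The matrix protein gene Ltbp2 was 2.84-fold lower at dim signals of 106 and 37.1, and Msx2 and Id1 lay at 0.46 and 0.41. Wnt response genes lay low, with 10 of 11 below 0, 3 at least 2-fold lower, 0 higher and a median of -0.58 at percentile 0.89, or -0.31 under quantile normalization. All but 1 of the 11 were dim genes. Znrf3, Sp5 and Wif1 were 2.45-fold, 2.32-fold and 2.10-fold lower. Sp5 lost its direction under quantile normalization. Lgr5 lay at 0.85.

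Results for matrix and contractile genes varied by list and by setting. No gene of the lens capsule and basement membrane passed 2-fold (0 of 16), with 8 above and 8 below 0 and a median of 0.01. Nid2 lay at 0.83, Col18a1 at -0.45, Col4a4 at -0.42 and Lama1 at 0.31. Of 11 genes of epithelial-mesenchymal transition only Acta2 passed 2-fold, and 5 lay above and 6 below 0. The list's median was -0.03 at percentile 28.8, and 0.44 at percentile 99.99 after loess. Fibronectin, Fn1, had a difference of 0.78, Tagln 0.50 and Itgav 0.45. Of the 5 measured mesenchyme markers 2 were at least 2-fold higher, and the median of 0.50 lay at percentile 99.79. The median turned to -0.15 over the brighter probes and to -0.15 without a filter on background. The fibrillar collagen genes Col3a1 and Col1a1 were 2.84-fold and 2.06-fold higher at dim knockout signals of 94.2 and 63.8, Col1a2 lay at 0.50 and Ogn at -0.29.

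Markers of cells next to the lens did not move as one. All 9 measured pigment cell markers lay below 0, with 2 at least 2-fold lower and a median of -0.40 at percentile 1.74, or -0.26 under quantile normalization. Ttr was 2.66-fold and Best1 2.03-fold lower at dim signals. The melanin enzyme gene Tyrp1 lay at -0.84 and Mlana at -0.45. Erythroid markers lay low without passing 2-fold (0 of 8), with 7 below 0 and a median of -0.28 at percentile 0.05. The globin genes Hbb-b2, Hbb-bs and Hba-a2 are near-identical to other globin genes, so their readings are uncertain. Hbb-b2 lay at -0.75, Alas2 at -0.50, Car2 at 0.34 and Hbb-bs at -0.32. Of 8 surface ectoderm and cornea markers 1 was lower, with a median of -0.50 and 0.14 under quantile normalization. Krt13 was 2.69-fold lower at dim signals, and Krt14, Sfn and Aldh3a1 lay at -0.96, -0.91 and -0.69. Of 10 vessel endothelium markers 1 was lower, Emcn at -1.12, with a median of -0.08, while Tek lay at 0.86 and Pecam1 and Esam both at -0.63. Of 9 macrophage markers 1 was lower, Ptprc at -1.06, with a median of -0.10 and 0.22 under quantile normalization. Ptprc was dim and lost its direction under quantile normalization. C1qc and Aif1 lay at 0.63 and -0.63, and Lyz1 at -0.48. Of 7 skeletal muscle markers 1 was lower, Tnnt3 at -1.22, with a median of -0.03 and 0.64 under quantile normalization, Acta1 at -0.91, Myh3 at -0.67 and Myh8 at 0.22. The Y-linked genes Ddx3y and Eif2s3y were measured on both arrays, with differences of -0.12 and 0.00, and Xist was not well above background on both.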

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

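All tests in this part were chosen after the imbalance among dim genes had been seen. Probes for ERCC control transcripts, which enter none of the comparisons, differed between the arrays. Their median processed signal was 17.1 on the control array and 3.16 on the knockout array, and 96 of 96 probes read higher on the control array. Both medians lay below the lowest spot signal called well above background on their array (20.6 and 12.1). Negative control spots had medians of 4.72 and 2.76, over 308 spots on each array.

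The pattern that this bears on is the count of 835 lower against 146 higher genes, of which 807 lower genes were dim. A loss of transcripts in the knockout lens at any signal level would give a majority of lower genes among bright named genes too. There they made up 31.8% of the 2-fold calls (exact 95% interval 22.3 to 42.6), but 42.9% after loess (32.1 to 54.1), 53.8% with the 75th percentile over measured probes (43.1 to 64.2) and 58.9% without a filter on background (50.3 to 67.1). The share depends on the setting. Relative to the median of bright genes it was 44.8% (34.1 to 55.9) under both the reported and the measured-probe 75th percentile. Without the filter, probes not above background entered the means of these genes, so 58.9% includes dim readings. The interval around 44.8% allows a minority or a majority of lower genes. A loss at any signal level therefore stays open. Bright probes without a gene symbol had 70.5% of their 2-fold calls lower (57.4 to 81.5), and from 70.5% to 77.6% in the settings other than the array medians. A higher residual background on the control array may account for the imbalance among the dimmest genes. E1A spike-in probes below a signal of 100, 3 in number, differed from bright ones by -2.43 on the log2 scale, a value that could have come out near 0. Those reading 3.59 and 6.86 on the knockout array lay below its lowest signal called well above background (12.1), unlike the measured genes. The third, from 81.0 to 38.3, differed by -1.07. Measured genes with a mean signal below 100 had a median difference of -0.39, so -2.43 overstates the shift for them. The next spike-ins, at control signals of 280.0 and 566, differed by only -0.07 and -0.21. Of the 807 dim lower genes 732 had a mean signal below 100, where 44 were higher. From there to the signal of the next spike-in 72 were lower and 37 higher, and how far the background reaches into that range is open. Among the 627 dim genes above it 3 were lower and 5 higher. The part of any true loss among dim genes cannot be separated from that background in this pair of arrays, since dim genes have no other reading.

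Probes without a gene symbol were not used in the comparisons, and 10971 of them were measured on both arrays. Of the 2882 that were at least as bright as the median gene, 18 were at least 2-fold higher on the knockout array and 43 at least 2-fold lower. Among the 1895 with a mean signal of at least 1000, 13 were higher and 23 lower. Over all measured unnamed probes, dim ones included, 55 were higher and 1902 lower.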

How the results depend on the processing

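Directions of the 24 bright genes taken by the naming rule were kept under all 13 alternatives of scaling, background and filter, and all 24 stayed at least 2-fold apart under each except the array medians, which left 12. Most of the 24 were read by 1 bright probe, whose value the filters and the brightest probe could not change. No scaling and the 75th percentile over measured probes moved every gene alike, by -0.01 and -0.13. Those settings tested little for these genes. Of the 60 higher and 28 lower bright genes, between 43 and 60 higher ones and between 1 and 28 lower ones stayed 2-fold apart. The cell cycle median ranged from 0.33 to 1.54. Relative to the median of all genes it ranged from 0.34 to 0.60. Foxp1 lay between -1.92 and -0.59. Normexp on the median signals and loess with the brighter probes were chosen after the data were seen. The planned normexp on mean signals was not run. Leaving out saturated probes removed none, so it tested nothing. No interferon response gene was left for the filter on brighter probes. No paired analysis was possible because each genotype had 1 array.

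Scaling by the array medians shifted the median of all genes by 1.08 and so moved each result by that construction, turning the sign of any gene lower by less than that. Foxp1 became -0.59, with 8724 higher and 101 lower genes, against 146 and 835 in the reported setting. List medians became 1.07 for crystallins, 1.12 for lens fibre genes, 0.98 for lens epithelium genes and 1.54 for cell cycle genes. Among genes named as 2-fold lower, Cdkn2a (0.0551), Wif1 (0.0111), Isg15 (0.0249), Best1 (0.0576) and Ptprc (0.0137) lay within that shift, which says nothing about them in particular. Taking the 75th percentile over measured probes shifted the median of all genes by -0.13 and put Foxp1 at -1.79.

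For the remaining settings the cause was not tested. Quantile normalization gave a Foxp1 difference of -1.54 with 776 higher and 232 lower genes, and turned Sp5 to 0.0107 and Ptprc to 0.21. Loess gave 259 and 381 genes, normexp -1.34 for Foxp1 with 72 and 99 genes, and the brightest probe of Foxp1 -1.82. Probes well above background on at least 1 array gave 256 and 2812 genes, and no filter 293 and 4466, since both admit dimmer genes. The brighter probes alone gave -1.83 for Foxp1 with 80 and 46 genes, and with loess added -1.92 with 67 and 52. A threshold of 1.5-fold gave 571 and 1822 genes and one of 3-fold 50 and 273. Of the 835 lower genes 807 were dim, 732 of them with a mean signal below 100.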

Other observations

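The list of retinal progenitor genes, the lists of ATF4 amino acid and of SRF and YAP target genes, and the tests of epithelial share, of single-probe faults, of the chromosome of Foxp1 and of neighbouring genes were chosen after the related results had been seen.

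Genes at least 2-fold higher on the knockout array lay next to each other in 8 pairs along the GRCm38.p6 gene order of the 14254 measured genes. Random sets of 146 genes gave 1.49 pairs on average, with 95% of sets between 0 and 4. Lower genes, most of them dim, formed 79 pairs against 48.7 for random sets of 835 (36 to 62). The random sets were drawn from all measured genes and were not matched on signal. The excess of lower pairs therefore cannot be told apart from neighbouring genes that are dim alike. The pairs named here were picked after their values were seen. Tnfsf9 and Cd70, neighbouring genes for ligands of the TNF family on chromosome 17, had differences of 3.24 and 3.33. Adamts1 and Adamts5, proteases of the extracellular matrix on chromosome 16, had differences of 1.11 and 1.40. Ppp1r15a, which restores translation after stress, and Plekha4 on chromosome 7 had differences of 1.56 and 1.58. The angiotensin-converting enzyme gene Ace and its neighbour Cyb561 had differences of 1.01 and 1.26. The spans of Omp and Capn5 overlap, so that pair is uncertain as separate readings. Neighbouring genes are often expressed together, and no explanation was tested for these pairs.

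Cell cycle genes were higher as a group on the knockout array, with a median of 0.46. A trend with signal would have left the median near 0 after loess, where it was 0.44. A larger share of epithelial cells, which hold the dividing cells of the lens, would raise epithelium genes alike, and these lay below the cell cycle median by a difference of -0.56 (bootstrap 95% interval -0.69 to -0.33). The epithelium list as a whole thus did not rise with the cell cycle genes, with 5 of 16 members above 0 and 11 below. That interval covers the spread over list members only, not differences between animals or dissections. More retinal tissue in the knockout sample stays open. Retinal progenitor genes differed from the cell cycle median by -0.17 with an interval of -0.33 to 0.13, and the brightest retina markers, Sncg and Stmn2, read 1770 and 1825 on the knockout array against 1071 and 997 on the control array. A change of proliferation with the Foxp1 genotype may also account for the group, but with 1 array per genotype it is confounded with a difference between animals.

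The largest differences raise a question about single probes and strain. All 11 genes at least 8-fold higher on the knockout array were read by 1 probe each, and 36.4% of them were dim genes. Noise of dim signals stays open for the 4 dim ones, since without further arrays nothing here decides it. Faults of single probes stay open too. Among 21 genes with several probes whose brightest probe was bright and at least 2-fold higher, the other probes were all at least 2-fold higher in 52.4% (exact 95% interval 29.8 to 74.3). For lower genes the share was 8.33% of 12 genes (0.21 to 38.5), so faults of single probes may account for many bright lower readings, although probes for different transcripts of a gene can also differ. Counting genes with at least 1 of several bright probes beyond 2-fold, every bright probe passed in 4 of 14 for higher and 1 of 14 for lower genes. Neither count covers genes read by 1 probe, such as all 11 above. Strain DNA carried along with the floxed allele would place these genes on chromosome 6 with Foxp1, and 0 of the 11 lay there (0%, exact 95% interval 0 to 28.5). Of the 200 measured genes nearest to Foxp1, 0 were bright 2-fold genes, at percentile 13.5 of all such windows, but a typical window held 1, so that count alone decides little. Strain differences elsewhere in the mixed background were not tested and may remain among the sources.

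A hypothesis that the ATF4 pathway may join Chac1, Trib3, Gdf15 and Cdkn1a was tested on other ATF4 genes of amino acid supply. The median of these 22 genes was 0.19 (bootstrap 95% interval 0.07 to 0.22), well short of the 0.5 set in advance, at percentile 99 of matched random lists. The hypothesis that Acta2 and Ccn2 may share the factors SRF and YAP was tested on 18 other target genes, whose median was 0.10 (-0.07 to 0.34), again short of 0.5. With Acta2 and Ccn2 included, the 20 measured genes of that list had a median of 0.17 at percentile 98.0. The cell cycle median of 0.46 would also have fallen short of 0.5. Both results therefore speak only against a shift of that size, and a smaller shared shift stays open. Why the genes themselves differed was not tested further.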
